A study of Mus musculus with 2 samples.

How the data were processed

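RNA was measured on 2 arrays, 1 from each group of induced neural progenitor cells. These cells were made from mouse embryonic fibroblasts with retroviral vectors of either 5 or 6 transcription factors, per the labels. The fibroblasts carried a hygromycin resistance cassette at an allele given only as Sox. Hygromycin was added 4 weeks after infection and the cells were harvested after 1 more week. Cy3-labelled cRNA was made from 0.25 ug of total RNA. The identities of the factors are not given in the sources used here. Arrays of neural progenitor cells, embryonic stem cells and fibroblasts, which the study clustered with these, were not analysed here.

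The deposited values were spot intensity on a linear scale, 1 file for each array and a table of both. Agilent Feature Extraction was used, per the submitters' processing notes, at version 10.7.3.1, per the file headers. Local background was subtracted, spatial trends were removed within each array, and the intensity near background was replaced by a surrogate, per the file headers. No scaling between arrays was recorded there. The authors' deposited table held the same processed intensity: 90036 of 90036 values over both arrays were equal within a relative tolerance of 1e-06. It was therefore linear and not centred, with column medians of 43.1 for 5 factors and 39.9 for 6 factors. Both arrays lay on the same slide and were scanned together. Culture, infection, RNA extraction and labelling cannot be told apart from the group, which has 1 array.

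Each array had 45018 spots, of which 43379 were not controls, for 41174 probes. Spots marked as outliers by the scanner software on either array were left out: 72 were marked with 5 factors and 89 with 6 factors. No spot was saturated. Log2 of the processed intensity was taken and the array's 75th percentile over non-control spots was subtracted, so that a normalised signal of 0 is that percentile (651 with 5 factors and 581 with 6 factors, in intensity). Spots of a probe were averaged. A gene was represented by its probe with the highest mean signal among those well above background on at least 1 array, a choice blind to the difference. A probe counted as well above background where at least 50% of its spots were. The log2 difference was 6 factors minus 5 factors.

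For a probe well above background on 1 array only, a rule gave a bound or kept the measured difference. The brighter value was set against the higher of the dim probe's own value and the lowest normalised signal among probes well above background on the dim array, which was -5.90 with 5 factors and -6.04 with 6 factors. Where that lowest signal was the higher, the result is a bound, written as "at least N-fold". Where the dim probe's own value was the higher, the result is the measured difference, printed with its error. Probes were named from their accessions and symbols through a RefSeq gene table of the GRCm38.p6 assembly, used for names only: 22951 matched by accession, 6659 by symbol and 3109 by a synonym, and 8455 kept the name in the files. Probe positions are those in the files, whose annotation build was mm7 per the file headers. No gene annotation of that build was used here, so exons and untranslated regions are not stated.

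With 1 array per group no test was possible and no p-value was computed. Genes were counted by a fixed rule of size, a difference of at least 2-fold. The error printed after ± combines the scanner software's error model over both arrays and the spots of a probe, and it holds no culture-to-culture variation. That model had a multiplicative term of 0.1, and its median error of a log2 difference was 0.20. Spread between spots was smaller: among 143 probes printed 10 times and well above background on both arrays, the median SD between spots was 0.06 with 5 factors and 0.06 with 6 factors. The difference of 78.3% of these probes exceeded 2 standard errors from their spots, so spot noise alone does not measure the precision of the comparison. The error after ± falls with the number of spots averaged. Probes printed 10 times therefore have smaller errors, which reflect spot number and not a more precise comparison of the cultures.

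The lists of genes, the rule of size, the rule for named genes, the scaling and its alternatives were chosen before the data were examined. The 29 lists covered neural, mesenchymal, pluripotent and other cell types, signalling pathways and stress responses, and named 552 different genes, 413 of which were well above background on at least 1 array. The median difference of each list was placed among the medians of 10000 random lists of the same size matched on signal in 20 bins. The percentile describes these 2 arrays and is no test. Named genes were the 15 largest differences in each direction among genes with a symbol of their own, above background on both arrays and of the same sign under each normalisation, and the 5 largest bounds in each direction. They also included up to 4 members of each list with the largest differences, up to 8 in the 3 lists of progenitor, fibroblast and pluripotency genes, and Sox2, Nes and Sox1 whatever their values. Some genes that this rule names are not reported here.

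The alternatives were scaling by the array's median, quantile normalisation, scaling by 320 spike-in spots, a loess on mean signal with a span of 0.3, and normexp background correction with an offset of 50 followed by quantile normalisation. The others were the authors' deposited table, the mean over a gene's probes, genes above background on both arrays only, no background filter, and thresholds of 1.5-fold and 4-fold. The calculation was tested on simulated arrays of 18172 genes with 200 changed ones. The changed genes were drawn only from those above background on both arrays with a signal above -3. All changed genes at a log2 change of 2 were called, and 97% of those at 1.5. Among 12364 unchanged genes with a signal above -3, 0 were called, against 16 of 17940 at any signal. The simulated noise followed the error model and held no culture-to-culture variation. These counts therefore give neither the recovery of dimmer genes nor the false calls in the real comparison. A simulated list of 32 genes shifted by 0.5 gave a median of 0.53 at the 100th percentile. R 4.3.3 with limma 3.58.1 was used for normexp, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 for the rest.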

Results

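Gene expression was profiled in mouse induced neural progenitor cells made from embryonic fibroblasts with either 5 or 6 transcription factors, on 1 single-colour array for each. Of the non-control spots, 63.2% were well above background with 5 factors and 64.6% with 6 factors. The comparison asks how cells made with 6 factors differ in expression from cells made with 5. There were no replicates, so no test was run, and "higher" and "lower" below refer to the fixed rule of size.

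Among the genes named by the rule, Tnfsf18, which encodes the ligand of the costimulatory receptor GITR, stood furthest apart. It was 90.4-fold lower with 6 factors, at a log2 difference of -6.50 ± 0.25. Hoxd13, a homeobox gene of posterior and distal limb identity, was 16.6-fold lower (-4.05 ± 0.33). In the other direction, the noncoding RNA Pantr1 was 13.6-fold higher with 6 factors (3.77 ± 0.21). Bcan, a chondroitin sulphate proteoglycan of brain matrix, was 5.45-fold higher, and the midbrain and hindbrain homeobox gene En2 was 4.96-fold higher. Most genes differed little, with a median absolute log2 difference of 0.11 over the 16656 genes above background on both arrays. Across those genes the arrays correlated at a Pearson r of 0.994 and a Spearman rho of 0.995, genes not being independent replicates.

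Counted by size, 494 genes were at least 2-fold higher and 230 at least 2-fold lower with 6 factors, out of 18095 genes well above background on at least 1 array. Of these, 221 higher and 96 lower genes were above background on both arrays, and the other 273 and 134 on 1 array only. The higher genes made up 68.2% of the total, and 57.4% (398 higher, 295 lower) under quantile normalisation. Dim genes supplied most of the count: among 11132 genes with a mean normalised signal of -2 or more, 29 were higher and 12 lower. A normexp background correction followed by quantile normalisation left 53 higher and 27 lower.

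**Figure D1:**
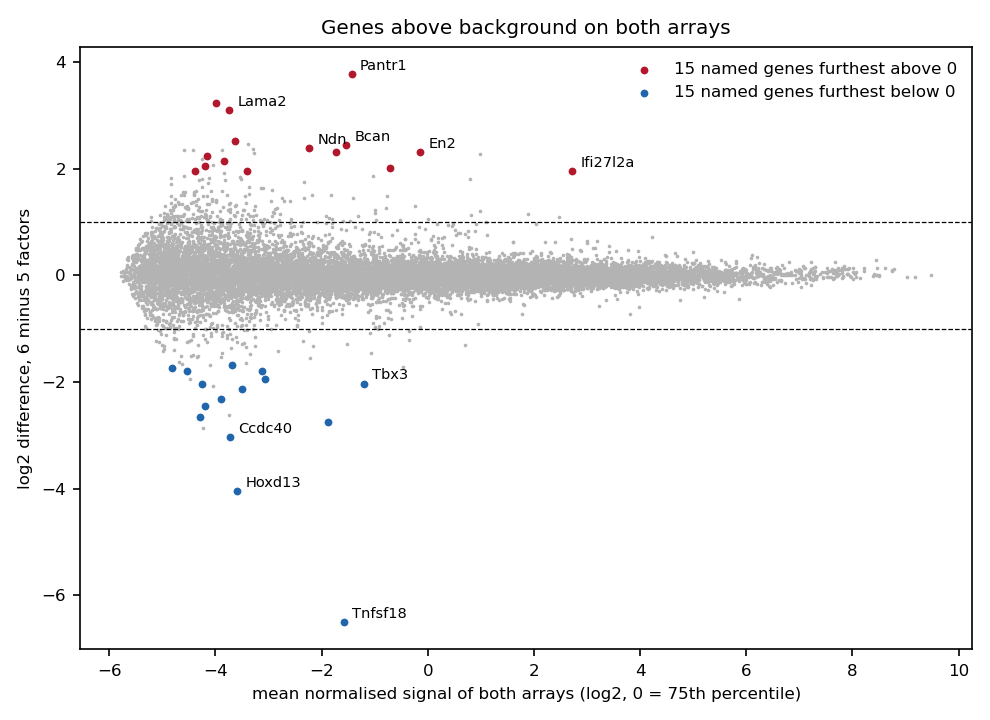
Log2 difference (6 minus 5 factors) against mean normalised log2 signal for the 16656 genes above background on both arrays, with dashed lines at 2-fold. Red and blue points are the 15 named genes furthest in each direction, led by Pantr1 (3.77) and Tnfsf18 (-6.50), and grey points beyond them are genes outside the naming rule; the scatter widens at low signal.

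The probe for Tnfsf18 lies on chromosome 1 from 161467197 to 161467256 (mm7), and its normalised signal was 1.67 with 5 factors and -4.83 with 6 factors. Below it among lower genes came Ccdc40, which is needed to assemble motile cilia (-3.04 ± 0.30), Prxl2b (-2.76 ± 0.21), Slc26a10 (-2.65 ± 0.34) and the kainate receptor subunit Grik4 (-2.45 ± 0.32). Egflam differed by -2.33 and Igfbp3 by -2.03, but another probe of each gave -0.24 and -0.30. The T-box factor Tbx3 (-2.03 ± 0.21), the copper carrier Cp (-1.94 ± 0.22) and the ETS factor Erg (-1.79 ± 0.22) were lower as well. Prr15l (-1.79), Pcbd1 (-1.73) and Trim61 (-1.68) closed the group together with the olfactory receptor Olfr522 (-2.14), a member of a large family of similar genes.

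Pantr1 is read by a probe on chromosome 1 from 42888651 to 42888710 (mm7), with a normalised signal of -3.31 with 5 factors and 0.45 with 6 factors. Lama2, a laminin chain of basement membrane, was 8.56-fold higher and its other probe gave a log2 difference of 1.88. Cd302 (2.52 ± 0.27), the imprinted gene Ndn (2.38 ± 0.21), Ppfibp2 (2.30 ± 0.21), Adgrf3 (2.23 ± 0.30) and the thromboxane synthase gene Tbxas1 (2.05 ± 0.28) were also higher, as was Fam209 (3.23 ± 0.32). The interferon-inducible gene Ifi27l2a had a normalised signal of 1.74 with 5 factors and 3.70 with 6, and its probes gave differences of 1.96 and 2.05. Galc gave 1.95 on its brightest probe and -0.37 on another. Rps4l (2.02), Vmn1r195 (2.15) and Olfr615 (1.95) belong to families of similar genes, so their identity is uncertain.

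Some genes were well above background on 1 array only. With 6 factors these included Slc51a, a subunit of a bile acid transporter (at least 21.0-fold higher), the signalling ligand Wnt3 (at least 14.4-fold on 1 probe, 0.47 in log2 on another), the chemerin-binding receptor Ccrl2 (at least 13.0-fold), Svs3a (at least 11.1-fold) and Ugt2b5 (at least 10.1-fold). With 5 factors only, Galnt17 was at least 12.6-fold brighter, Myom3 at least 8.45-fold, Olfr173 at least 8.26-fold and Ankrd55 at least 7.20-fold. The nucleoside transporter Slc28a3 was at least 11.9-fold brighter with 5 factors, but its probe measured on both arrays gave 0.32, so its direction is unsettled.

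Of 29 neural progenitor markers on the array, 18 were well above background, 3 were higher with 6 factors and 0 were lower. The higher ones were Bcan (2.45 ± 0.21), Rfx4 (1.84 ± 0.26, and 0.68 on its other probe) and Prom1 (1.10 ± 0.21). Sox2, a core progenitor factor read on chromosome 3 from 34459231 to 34459290 (mm7), differed by -0.78 ± 0.22, short of 2-fold. The intermediate filament gene Nes differed by -0.11 ± 0.06 and Sox1 by 0.27 ± 0.22. Cdh2 (-0.66), Lhx2 (-0.63) and Olig2 (-0.51) were under 2-fold. The median of the list was 0.06 (0.01 to 0.07 over scalings), at the 90.5th percentile of random lists. Among 11 markers not well above background on either array were Pax6, Sox3, Fabp7, Hes5 and Pou3f2.

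Other neural lists held single genes that differed within small medians. Of 13 measured oligodendrocyte lineage markers, Sox10 (1.83 ± 0.29) and Cspg4 (1.40 ± 0.22, but -0.46 on another probe) were higher, and the median was 0.11 (93.9th percentile; 0.05 to 0.13 over scalings). Neural crest and Schwann cell markers, which share Sox10, had 3 of 11 higher, Tfap2b (1.28 ± 0.32) among them; their median was 0.04, and -0.01 to 0.11 over scalings. Of 16 astrocyte markers only Ntsr2 was higher (1.23 ± 0.33), with a median of 0.06 (0.00 to 0.07 over scalings). Sox10, Tfap2b and Ntsr2 were dim with 5 factors, at normalised signals of -5.03, -5.21 and -5.14. The lowest signal well above background on that array was -5.90. Among 18 neuron markers 0 were higher, and Slc17a6 and Stmn2 were at least 3.46-fold and at least 3.26-fold brighter with 5 factors (median -0.07, 11.6th percentile; -0.13 to -0.06 over scalings). Of 15 forebrain and midbrain patterning factors, En2 (2.31 ± 0.06) and Lmx1b (1.17 ± 0.44) were higher, with a median of 0.06 (0.00 to 0.08 over scalings). Lmx1b was above background with 6 factors only. Of 16 factors used in fibroblast-to-neural conversion, Rfx4 alone was higher, with a median of 0.01 that ran from -0.05 to 0.02 over scalings. Because the factors in the vectors are not named, it is not known whether these probes, including those of Sox2 and Sox1, also read vector transcripts. These list medians lay within the central 95% of random lists, although the oligodendrocyte list reached the 99.1th percentile under another scaling.

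Of 35 fibroblast and mesenchymal markers 32 were measured, 5 were higher and 0 lower with 6 factors. Members lay on both sides of 0, 17 above and 15 below, with a median of 0.01 (-0.05 to 0.06 over scalings) at the 61.7th percentile (57.2 to 97.4 over scalings). The higher ones were the lysyl oxidase family genes Loxl1 (1.57 ± 0.26) and Lox (at least 2.29-fold), Pdgfrb (at least 2.48-fold), Thy1 (1.15 ± 0.20) and Thbs2 (1.00 ± 0.26). Acta2, the smooth muscle actin, differed by -0.73 ± 0.06, with its probes between -1.55 and -0.27, and Fap by 0.73 ± 0.20. Of 23 pluripotency genes 15 were measured, and only Tbx3, also active outside pluripotent cells, differed 2-fold. Dppa2 differed by 0.99 ± 0.21, and Nanog was above background with 6 factors only, at least 1.86-fold brighter. Pou5f1, Dppa3, Lin28a and Gdf3 were not well above background on either array. The pluripotency median was 0.18, at the 94.8th percentile; over scalings it ran from 0.05 to 0.18 and its percentile from 71.5 to 94.8.

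Among 21 measured Hox genes, Hoxd13 was lower and Hoxb8 higher (at least 2.87-fold), and the list's median was 0.01 (-0.04 to 0.01 over scalings). The probe of Hoxd13 lies on chromosome 2 from 74514907 to 74514966 (mm7). Its other probe was above background with 5 factors only and gave a bound of -1.58. Along the HoxD cluster, Hoxd10 differed by -0.95 ± 0.20 and Hoxd9 by -0.43 ± 0.20, while Hoxd3, Hoxd4 and Hoxd8 gave -0.11, 0.12 and 0.03; Hoxd11 and Hoxd12, between Hoxd10 and Hoxd13, were not well above background on either array. In the HoxA cluster the posterior genes Hoxa10, Hoxa11 and Hoxa13 gave 0.06, 0.05 and 0.18.

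**Figure D2:**
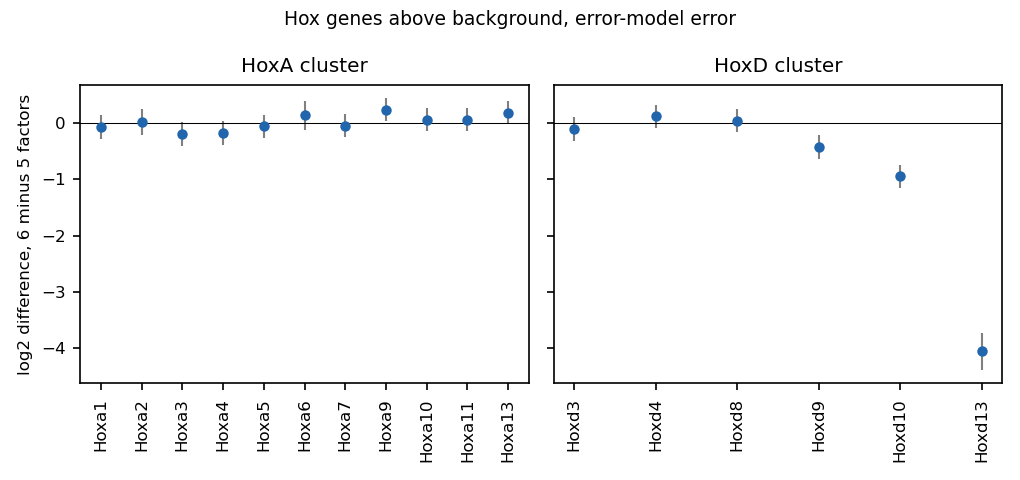
Log2 difference (6 minus 5 factors) of the measured genes of the HoxA and HoxD clusters in cluster order, with bars for the error-model error. HoxA genes lie between -0.20 and 0.23, and HoxD genes run from 0.12 for Hoxd4 to -4.05 for Hoxd13.

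Of 25 measured interferon-stimulated genes, 23 had a log2 difference above 0, 20 were under 2-fold and 5 were at least 2-fold higher with 6 factors: Ifi44 (1.92 ± 0.26, and 0.66 on its other probe), the ISG15 protease Usp18 (1.51 ± 0.21), Rtp4 (1.21 ± 0.20), the chemokine Cxcl10 (1.11 ± 0.21) and the ubiquitin-like modifier Isg15 (1.02 ± 0.21). Ifit2 (-0.51 ± 0.20) and Tap1 (-0.06 ± 0.21) were the exceptions. The median of 0.54, 1.45-fold, lay at the 100th percentile of random lists and ran from 0.30 to 0.56 over scalings.

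Other signalling and metabolic lists lay outside the central 95% of random lists, with small shifts. TGF-beta and BMP targets had 13 of 16 members above 0 but 0 at 2-fold, and a median of 0.23 (100th percentile; 0.12 to 0.24 over scalings), with Atoh8 at 0.51, Tgfbi at 0.46 and Id1 at 0.33. Wnt pathway targets had 10 of 13 members below 0 and a median of -0.16 (0.800th percentile); the largest were Sfrp2 (-1.05 ± 0.21) and Sfrp1 (-0.93 ± 0.21), secreted antagonists of Wnt ligands, while Lgr5 and Lef1 gave 0.69 and 0.60. Hypoxia and glycolysis genes had 17 of 19 members below 0 and 0 at 2-fold, with a median of -0.09 (0.810th percentile, reaching 6.65 under another scaling; -0.15 to -0.06 over scalings), with Car9 at -0.54 and Eno1 at -0.30. If genes varied independently, 1.45 of the 29 lists would lie outside that range, against 4 here, 3 of them under every scaling. Members of a list can vary together between cultures, so this comparison is no test.

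**Figure D3:**
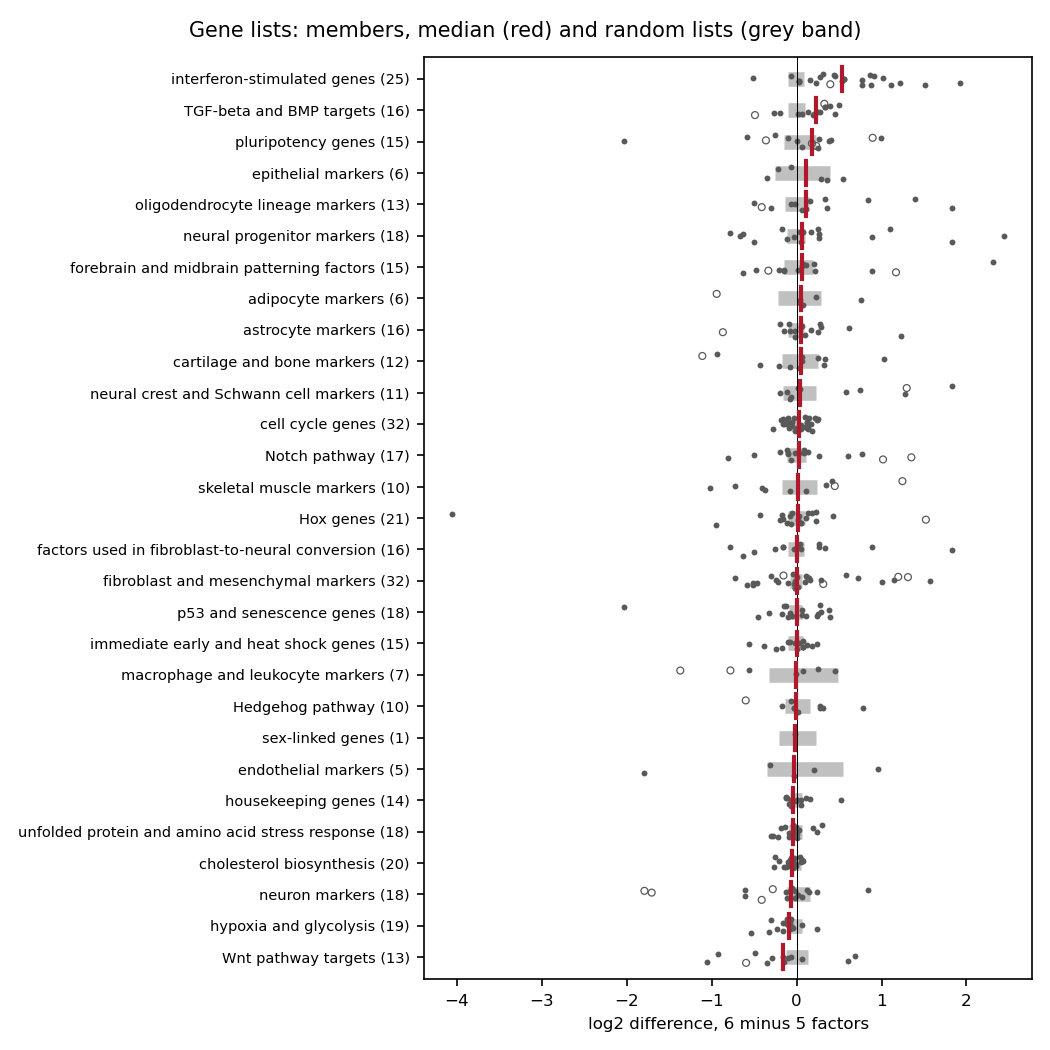
Log2 difference (6 minus 5 factors) of the measured members of each of 29 gene lists, with the number measured; open circles are bounds or genes above background on 1 array only, red lines medians and grey bands the central 95% of random lists. Interferon-stimulated genes have the highest median (0.54) and Wnt pathway targets the lowest (-0.16).

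The remaining lists had medians inside that range. Of 32 cell cycle genes, 0 differed 2-fold and the median was 0.03 (-0.03 to 0.05 over scalings), with Aurka at 0.26 and Ttk at -0.27. Of 18 p53 and senescence genes only Igfbp3 differed (median 0.00). Notch pathway genes had 2 of 17 higher, Heyl (1.35 ± 0.41) and Dll3 (1.02 ± 0.43), with a median of 0.03. Both were above background with 6 factors only. Hedgehog pathway genes (median -0.00 over 10), cholesterol biosynthesis genes (-0.06 over 20), unfolded protein and amino acid stress genes (-0.04 over 18), immediate early and heat shock genes (0.00 over 15) and housekeeping genes (-0.04 over 14) held no 2-fold member. Medians of the p53, Notch, Hedgehog and immediate early lists changed sign over scalings.

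Markers of other cell types were mostly dim. Of 18 macrophage and leukocyte markers 7 were measured, 0 were higher, and Cx3cr1 was at least 2.58-fold brighter with 5 factors (median -0.00). Endothelial markers had 5 of 12 measured, with Erg lower (median -0.03), and 6 of 16 epithelial markers were measured with none at 2-fold (median 0.11, and -0.05 under normexp). Among 10 skeletal muscle markers (median 0.02), Acta1 was lower (-1.01 ± 0.21). Pax7 was higher (1.25 ± 0.41) and above background with 6 factors only. Among 12 cartilage and bone markers (median 0.05), Col11a1 was higher on its brightest probe (1.03, and -0.87 on another). Spp1 was lower (-1.11 ± 0.15) and above background with 5 factors only. The muscle and cartilage medians also changed sign over scalings. Adipocyte markers had 0 of 6 at 2-fold (median 0.06). Of 5 sex-linked genes only Xist was measured, at -0.02 ± 0.20 (0.14 under normexp), and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were not well above background on either array.

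By position, the genes of chromosome 8, among them Sox1 and Trim61, had a median of -0.098 over 837 genes above background on both arrays, and the next largest median of any chromosome was 0.042 in size. The difference between these arrays has no replicate check, so variation between cultures is not separated from the number of factors. Of 67 genes with several probes that differed at least 2-fold, 15 had probes of opposite sign, and only 23 had every probe at least 2-fold the same way.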

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

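All alternatives here were planned, and no test in this part was chosen after its result was seen. No paired analysis was possible because the labels give the 2 arrays no replicate numbers and each group has 1 array. The authors' deposited table holds the same values as the scanner files, so its agreement tests nothing. Counts of genes at least 2-fold different stayed within 1.5 times the main ones under the other scalings, the loess and the mean over probes. They moved to 53 higher and 27 lower with normexp followed by quantile normalisation, and 52 and 26 of these were among the main ones. Quantile normalisation alone gave 398 and 295, so it does not by itself account for that fall. The normexp correction and its offset were not separated. With genes above background on both arrays the counts were 221 and 96. Without a background filter they were 1560 and 759, since dim probes then enter at their measured values. Thresholds of 1.5-fold and 4-fold gave 1137 higher and 658 lower, and 78 higher and 41 lower. The neural progenitor median moved from 0.06 to 0.0056 under median scaling. The fibroblast median moved from 0.01 to -0.048 under median scaling, -0.044 under spike-in scaling and 0.060 under normexp. The pluripotency median moved from 0.18 to 0.045 under quantile normalisation, 0.059 under normexp and 0.069 both for genes above background on both arrays and without the filter. The correlation across genes moved from 0.994 to 0.997 with normexp and 0.990 without the filter. Slc28a3 was reversed, to 0.32, for probes above background on both arrays, because another probe then stands for the gene. Of the 68 named genes at 2-fold, 31 stayed at 2-fold with normexp. Over all lists and alternatives, 219 medians were the same within the spread of random lists and 42 moved. The 219 include the medians of all 29 lists under the deposited table, which are the same by construction. Signal over background limits the rest: 0.368% of genes with a signal of -2 or more differed 2-fold, against 724 of 18095 genes at any signal. Causes not named here were not tested.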

Other observations

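The tests chosen only after their results were seen were those of scaling on the share of higher genes, of brightness and of macrophage markers on the interferon genes, of the other Hoxd13 probe and Hoxa13, of the size of chromosome medians, and of chance on chromosome 8. The lists of further interferon-stimulated genes, imprinted genes and HoxD neighbours were drawn up after those patterns were noticed, but before the values of their other genes were seen. The exceptions are 2 imprinted genes: Ndn, which prompted its list, and Cdkn1c, also in the planned p53 and senescence list. How the tests of HoxD neighbours and of imprinted genes were read was adjusted after their values were seen.

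Among imprinted genes, Ndn was not alone: Magel2, its neighbour in the Prader-Willi region of chromosome 7, was 2.84-fold higher with 6 factors (1.51 ± 0.31). Mkrn3, Peg12 and Snrpn of the same region gave -0.03, 0.00 and 0.11. The 18 measured imprinted genes had a median of 0.11 (99.2nd percentile), with Mest at 0.64 and Peg3 at 0.37. That median and percentile include Ndn, which prompted the list, so they are not independent of it. Apart from Ndn only 1 of 17, or 5.88% (exact 95% interval 0.149% to 28.7%), differed 2-fold. Pou3f3, a neural POU factor gene that lies beside Pantr1 on chromosome 1, was among the planned progenitor markers. It was singled out only after the value of Pantr1 was seen. Its brightest probe gave 0.07 ± 0.35 and another gave 1.70. A further set of 25 measured interferon-stimulated genes included Lgals3bp (0.82 ± 0.20), Parp9 (0.60 ± 0.21), Herc6 (0.42 ± 0.21) and Eif2ak2 (0.39 ± 0.20), and 0 of the 25 reached 2-fold. Among genes with a signal of -2 or more, 70.7% of those at 2-fold were higher (exact 95% interval over genes 54.5% to 83.9%), and 57.4% was the lowest share of higher genes over scalings. Both intervals in this paragraph treat genes as independent, which they are not, and hold no variation between cultures.

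The interferon-stimulated genes may reflect a shared response that was stronger in the 6-factor culture. The further set had a median of 0.17, with 23 of 25 above 0, against -0.10 to 0.09 in the central 95% of random lists. Weak signal alone is argued against by the 18 brighter members, whose median was 0.49. Macrophages or leukocytes in the culture are argued against too: 0 of their 18 markers, 7 of them measured, were 2-fold higher, and the abundant transcripts Lyz2, Tyrobp and Laptm5 were not well above background on either array. The vectors, the factors they carry and a difference between single cultures cannot be told apart with 1 array per group, and none was tested.

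The low Hoxd13 value is unlikely to come from a faulty probe, since the second probe gave a bound of -1.58. A loss of cells of distal limb origin might lower Hoxa13 as well, but that gene gave 0.18 ± 0.21, and -0.13 on its other probe. Its normalised signal was weak, at -2.74 with 5 factors and -2.55 with 6 factors. The error holds no culture-to-culture variation, so this 1 gene cannot exclude such a loss. A change as large as that of Hoxd13 over the whole HoxD neighbourhood is argued against by the 6 flanking genes. They ran from Chn1 at -0.69 to Evx2, next to Hoxd13, at 0.43. Hoxd3, Hoxd4 and Hoxd8 within the cluster had a median of 0.03. A small change over the neighbourhood stays open, since the flanking genes had a median of -0.14 with an SD of 0.37 between them. The values of Hoxd9, Hoxd10 and Hoxd13, with Hoxd11 and Hoxd12 between them not well above background on either array, could, as a hypothesis, mark a difference in the posterior end of the cluster, which replicate cultures would have to show and which was not tested.

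Genes of chromosome 8 showed a small shift of their median, while 9 of 837 were at least 2-fold lower and 9 at least 2-fold higher. The median of -0.098 lay below each of 10000 random sets matched on signal (lowest -0.035). Chromosome 5, at -0.042 over 1052 genes, also lay below that lowest value. The random sets therefore do not cover ordinary spread between chromosomes, and chance is not excluded by them. On chromosome 8, 71.9% of genes lay below 0 against 51.1% elsewhere. Relative to other chromosomes, its median stayed at -0.077 or below under quantile normalisation, loess and normexp, the settings that do not shift all genes alike. Each of 4 consecutive parts of the chromosome lay below its random range, the closest to 0 at -0.078. These values argue against a trend with signal and against a single region. A candidate explanation is a different copy number of chromosome 8 in some cells of either culture, which was not tested, since genomic DNA was not analysed here. The median lay short of 0.3 in size, the mark assumed for a gain or loss in most cells, but the shift per copy was not measured on these arrays, so the share of cells stays open.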
